A study of Homo sapiens with 2 samples.

How the data were processed

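The data came from 1 culture of HMC3, an immortalised human cell line that its suppliers list as microglial. The line carried CRISPR interference machinery, a nuclease-dead Cas9 joined to the KRAB repressor, which lowers transcription near the site a single guide RNA (sgRNA) binds. Per the labels' protocols, the cells received a lentiviral pool of 269 sgRNAs at a multiplicity of infection below 0.1, were selected with puromycin, sorted for the BFP marker on day 6 and collected on day 12. They were then run over 12 lanes of a droplet-based 3′ single-cell kit that also captures the sgRNAs. The pool held 227 sgRNAs for 76 candidate regions, 19 sgRNAs for the transcription start sites (TSS) of 7 targets and 23 non-targeting sgRNAs. Not all regions were purely non-coding, since placed sgRNAs of some, rs34173062 among them, lay in coding exons. Of the regions, 75 had 3 sgRNAs and 1 had 2. Every TSS target had 3 sgRNAs except SYVN1, which had 1.

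The authors processed the reads with Cell Ranger 7.1 against GRCh38, per the submitters' processing notes. The deposited matrix held UMI counts per gene or sgRNA and cell barcode, without normalization, for 36601 genes and 96639 barcodes. The second deposited table gave the number of sgRNAs called in each barcode, with their UMI counts. The threshold behind those calls and the gene annotation release are not given in the sources used here. No column belonged to a sample outside the series.

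A cell was used if exactly 1 sgRNA was called in it, at least 500 genes were detected and at most 20% of its UMIs were mitochondrial. These filters were set before the data were examined, as were the test of each comparison, the gene lists and most alternatives. The shuffles of sgRNA labels and some tests of explanations were chosen later, as the closing section says. They left 64122 of the 64148 barcodes with 1 called sgRNA. Barcodes with 2 or more sgRNAs were kept out of the comparisons of the report, which is also how droplets with 2 cells were treated, and entered 1 alternative. No doublet caller was run. Counts were summed per sgRNA over its cells, and the 269 sums were the units of every comparison in the report. Cells were not treated as replicates there, and the closing section's intervals over cells or UMIs cover counting error only. Each sum came from 25 to 567 cells and held 326256 to 6901061 UMIs.

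The sgRNAs of a target are separate vectors in 1 culture and 1 transduction. The p-values therefore measure the spread between sgRNAs within this culture, which edgeR's fit pools over all targets. Nothing measured here covers other cultures. The single SYVN1 sgRNA has no replicate check and was assumed to vary like the sgRNAs of other targets.

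Genes with a mean count of at least 10 per sgRNA sum were tested, which kept 10635 genes and 99.3% of the UMIs. Counts were scaled with TMM factors (0.969 to 1.03) and fitted with edgeR 4.0.16 (R 4.3.3) as 1 group per target over all sums. Each target was compared with the 23 non-targeting sgRNAs by edgeR's two-sided quasi-likelihood test. The common biological coefficient of variation between sgRNAs was 3.21%. Log2 fold changes are those of edgeR's fit, with the standard error (SE) of the fit, and log2 CPM values carry a prior count of 2. P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05. The families were the own genes of the TSS targets, the region-gene pairs, all genes of 1 target, and TSPAN14 over the 76 regions. Beside these, an exact two-sided permutation test compared log2 CPM between a target's sgRNAs and the 23 non-targeting sgRNAs. With 3 sgRNAs it makes 2600 splits and cannot go below 0.000385. CPM values are given as mean ± SD over sgRNAs.

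To place the regions, each spacer was matched to the GRCh38 transcripts of GENCODE 29 with an adjacent NGG motif. This placed 41 region sgRNAs in 18 of the 76 regions and 11 TSS sgRNAs. No sgRNA of the other regions could be placed in those transcripts, so their coordinates are not given and their neighbouring genes were not tested as pairs. Pairs joined a placed region to each tested gene whose TSS lay within 1 Mb, which gave 479 pairs over 345 genes. For these distances the TSS was the outermost annotated 5′ end of the gene, and starts of its other transcripts were not used. Another 1290 pairs had a gene under the count minimum or outside the matrix.

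The 24 gene lists were fixed before the data were examined. Each of the 16 with at least 3 tested genes was tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and again with an estimated correlation. This was done for the 7 TSS targets and the 4 regions with a called pair, 176 tests in all. Numbers of cells per sgRNA were compared on the log2 scale by a permutation test with 100000 resamples, or by the exact test for single targets.

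Genes are named by a rule set before the data were examined: the own gene of each TSS target, the region-gene pairs past the threshold, and TSPAN14. For the 4 TSS targets and 2 regions with most calls, it adds up to 10 higher and 10 lower genes with a mean count of at least 50 and every sgRNA on 1 side of the non-targeting mean. It also names up to 4 members per described list. Any other gene is marked as chosen after its values were seen. The levels of some marker genes are not reported.

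The test was tested on simulated counts for 10556 genes, with 200 of them changed under the rs70602 region. It recovered 94% of the genes set to a log2 change of −1, 78% at −0.5, 90% at 0.5 and 100% at 1. Among its 195 calls 14 were unchanged genes, and 5 calls fell in the 82 unchanged targets. The simulated sgRNAs held no single sgRNA with outlying genes, as the real data do, so false calls of that kind are not measured by it. In the real data shuffled sgRNA labels gave up to 23 changes under regions.

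The alternatives covered other scalings, DESeq2 1.42.0, limma-trend, other gene and cell filters, sgRNAs left out in turn, other controls, lanes 1 to 6 or 7 to 12 alone, other windows and other adjustments. A value given without a named sgRNA comes from a fit that left out the sgRNA of the same position in every TSS target and region. Scaling, spread and adjustment were refitted as well, so a lost call need not be due to the named sgRNA alone. Figures were drawn with matplotlib 3.10.9, and other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.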

Results

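The study asked which genes change when non-coding regions at Alzheimer's disease risk loci are repressed in a human microglial line, and its title names TSPAN14. Both libraries came from 1 culture: 1 held the mRNA of single cells and 1 the sgRNA of each cell. The culture yielded 96639 cell barcodes over 12 lanes. Exactly 1 sgRNA was called in 64148 of them (66.4%), 2 or more in 19416 (20.1%) and none in 13075 (13.5%). The 64122 cells used held 778423829 UMIs, with a median of 11258 UMIs, 3470 genes and 1.06% mitochondrial UMIs per cell, and a median of 676 UMIs of the sgRNA itself. Non-targeting sgRNAs were in 4702 cells, TSS sgRNAs in 3780 and region sgRNAs in 55640. SYVN1, with 1 sgRNA, has no replicate for any value given under it.

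HMC3 cells in this culture expressed mesenchymal genes strongly, and the microglial markers named here at low levels. Among microglial identity genes, CD68, a lysosomal glycoprotein of macrophages, stood at 10.2 ± 2.18 CPM in cells with non-targeting sgRNAs (mean ± SD, n = 23 sgRNAs), and MERTK, a receptor for apoptotic cells, at 2.91 ± 1.12 CPM. Of 21 fibroblast and pericyte genes, 13 reached 10 CPM. The highest were LGALS1, a galectin, at 3241 ± 89.5 CPM, VIM, the mesenchymal intermediate filament, at 2771 ± 117 CPM and TAGLN, an actin-binding protein of smooth muscle, at 1968 ± 141 CPM. These are levels and no test was made.

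Markers of other cell types were mostly low, with single exceptions. KRT18, a keratin of simple epithelia, stood at 853 ± 42.3 CPM and its partner KRT8 at 58.6 ± 6.59 CPM, against 0.621 ± 0.666 CPM for CDH1, the epithelial cadherin. Among neuronal genes TUBB3, a tubulin, reached 56.1 ± 3.43 CPM, followed by SYT1 at 3.74 ± 1.32 CPM and SNAP25 at 3.03 ± 0.998 CPM, both of the synaptic vesicle release machinery. Among astrocyte genes, GJA1, a gap junction protein, reached 18.0 ± 2.25 CPM, SLC1A3, a glutamate transporter, 9.80 ± 2.05 CPM and SOX9 3.58 ± 1.47 CPM. Of the oligodendrocyte lineage, CNP reached 25.2 ± 3.84 CPM, with MBP, a myelin protein, at 1.48 ± 1.24 CPM. VCAN, a matrix proteoglycan, was the only gene of the other myeloid list above 10 CPM, at 20.6 ± 5.73 CPM, with ITGAX at 0.0976 ± 0.196 CPM and MRC1 at 0.0541 ± 0.144 CPM. No endothelial or lymphocyte gene reached 1 CPM: the highest were ERG at 0.951 ± 0.747, PECAM1 at 0.230 ± 0.710 and CDH5 at 0.210 ± 0.341 CPM, and CD4 at 0.189 ± 0.298, CD79A at 0.142 ± 0.265 and CD8A at 0.0121 ± 0.0581 CPM. A count of 0 in the non-targeting cells allows up to 0.0523 CPM, for counting error only. Of 88 genes at Alzheimer's risk loci, 35 reached 10 CPM, led by COX7C, a subunit of respiratory complex IV, at 625 ± 19.9 CPM, SEC61G, part of the protein translocation channel, at 483 ± 18.4 CPM and FERMT2, an integrin activator, at 141 ± 10.1 CPM.

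The TSS sgRNAs test whether the repressor lowers the gene it is sent to. Of 8 own genes, 7 were lower under their sgRNAs past the threshold, and SYVN1 was not. The SE of the fit pools the spread between sgRNAs over all targets. It does not measure how far the sgRNAs of 1 target differ, which the SDs of the CPM values give. BIN1, a membrane-bending adaptor of endocytosis, fell to 15.7 ± 15 CPM from 36.4 ± 3.68 CPM (log2 fold change −1.47 ± 0.17 SE, adjusted p = 6.29e-20 by edgeR). RAB1A, a GTPase of transport from the endoplasmic reticulum (ER) to the Golgi, fell to 36.1 ± 19.8 from 80.2 ± 6.49 CPM (−1.15 ± 0.10, 1.27e-27), and CLU, a secreted chaperone, to 2.49 ± 2.09 from 8.79 ± 2.24 CPM (−1.62 ± 0.37, 3.49e-07). SNX1, a sorting nexin of the endosome, fell to 16.9 ± 17.5 from 31.8 ± 4.83 CPM (−1.15 ± 0.18, 1.99e-11). TSPAN14 (ENSG00000108219), a tetraspanin that escorts the protease ADAM10, fell to 21.0 ± 10.7 from 40.9 ± 5.17 CPM (−1.03 ± 0.13, 5.72e-16).

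The sgRNAs at the shared promoter of RPA1 and SMYD4 gave the smallest of the called changes. RPA1, a subunit of the single-stranded DNA binding complex of replication, fell by 0.26 ± 0.08 on the log2 scale (adjusted p = 0.00225 by edgeR), to 71.7 ± 2.62 from 87.7 ± 7.16 CPM. SMYD4 fell by 0.34 ± 0.16 (0.037), to 13.8 ± 5.65 from 20.6 ± 2.72 CPM. RPA1-SMYD4_2 held few counts, 24 UMIs of RPA1 and 4 of SMYD4. It weighs as much as the other sgRNAs in the CPM means and the exact test. The fit weighs sgRNAs by their counts, so its change of SMYD4 is smaller than the CPM means imply. SYVN1, the ubiquitin ligase of ER-associated degradation, stood at 31.3 CPM under its sgRNA against 33.7 ± 4.82 CPM (log2 −0.12, 95% interval −0.39 to 0.15, adjusted p = 0.395 by edgeR). The exact permutation test (n = 3 sgRNAs against 23) gave 0.000385 for RAB1A, CLU and RPA1, the smallest p it allows, 0.00115 for TSPAN14, 0.00269 for BIN1, 0.005 for SMYD4 and 0.00769 for SNX1. SYVN1 (n = 1) had an exact permutation p of 0.708.

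Single sgRNAs of 1 gene differed widely. BIN1_1 left BIN1 at 90.4% of the non-targeting mean, while BIN1_2 and BIN1_3 left 15.3% and 23.7%. SNX1_1 left SNX1 at 115%, while SNX1_2 and SNX1_3 left 10.8% and 33.0%. RPA1-SMYD4_1 left SMYD4 at 97.4%. Without BIN1_1 the log2 change of BIN1 was −2.41, and without BIN1_2 it was −0.91. Without CLU_1 that of CLU was −2.69. Without SNX1_1 that of SNX1 was −2.24, and without SNX1_2 it was −0.52, and all of these stayed past the threshold. The placed TSS sgRNAs (GRCh38) lay in the 5′ UTR of BIN1 (chromosome 2, 127106977 to 127107084), CLU (chromosome 8, 27614687 to 27614910), RAB1A (chromosome 2, 65130044 to 65130213) and TSPAN14 (chromosome 10, 80454318 to 80454337). The placed sgRNAs of RPA1 and SMYD4 (chromosome 17, 1829988 to 1830113) spanned 5′ UTR and coding sequence, and SNX1_1 lay in a coding exon of SNX1 (chromosome 15, 64096145 to 64096164). The SMYD4 call ended without RPA1-SMYD4_3 (−0.08, adjusted p = 0.658 by edgeR) and without RPA1-SMYD4_2 (−0.32, 0.0552), and reached −1.07 without RPA1-SMYD4_1. With all cells with at least 1 called sgRNA SMYD4 stood at 0.019, and in lanes 7 to 12 alone RPA1 missed the threshold (−0.18, adjusted p = 0.123 by edgeR).

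**Figure D1:**
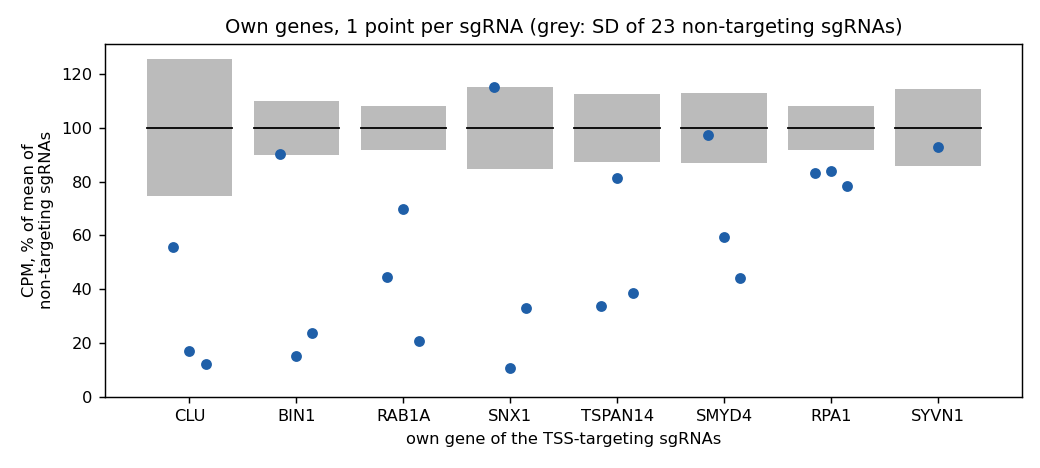
CPM of the 8 own genes of the TSS targets as a percentage of the mean of the 23 non-targeting sgRNAs, 1 point per sgRNA, with grey boxes for the SD of the non-targeting sgRNAs around a black line at their mean. BIN1_1 (90.4%) and SNX1_1 (115%) lie near the non-targeting mean, and BIN1_2 (15.3%) and SNX1_2 (10.8%) far below it.

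The region sgRNAs ask which nearby genes depend on each candidate region. Of 479 region-gene pairs in the 18 placed regions, 6 passed the threshold, 5 of them lower. Only transcripts were searched, so every placed region held exonic sequence. In the TSPAN14, SLC39A13 and SHARPIN pairs the placed sgRNAs lay inside the gene itself. There the test cannot tell a role of the region from repression of the gene at the site bound. TSPAN14 fell to 18.2 ± 3.37 CPM from 40.9 ± 5.17 CPM under the region named for rs7080009, rs1870138 and rs1870137 (log2 −1.14 ± 0.14, adjusted p = 2.3e-15 by edgeR). SLC39A13 (ENSG00000165915), a zinc transporter of the secretory pathway, fell to 12.5 ± 4.95 from 26.4 ± 3.38 CPM under rs11039225 (−0.98 ± 0.13, 2.86e-12). SHARPIN (ENSG00000179526), a subunit of the linear ubiquitin ligase complex, fell to 13.7 ± 12.2 from 33.6 ± 4.22 CPM under rs34173062 (−1.15 ± 0.17, 2.6e-11).

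The rs34173062 sgRNAs moved 2 more genes of chromosome 8. MAF1, a repressor of RNA polymerase III, fell to 47.4 ± 13.9 from 68.3 ± 6.47 CPM (−0.47 ± 0.09, 3.81e-05), and ZC3H3, an mRNA export factor, rose to 59.3 ± 12.6 from 40.3 ± 5.49 CPM (0.52 ± 0.10, 3.81e-05; both by edgeR). These sgRNAs lay in the 5′ UTR and a coding exon of SHARPIN (144103631 to 144103848), 4.38 kb from the outermost annotated 5′ end of the gene. Starts of other SHARPIN transcripts were not used, so this distance does not place the sgRNAs away from a promoter. The TSS of MAF1 is 0.760 kb away and that of ZC3H3 562 kb. Of the 3 sgRNAs, rs34173062_2 left SHARPIN at 81.4%, MAF1 at 92.2% and ZC3H3 at 113% of the non-targeting mean, while rs34173062_7 left 11.8%, 52.8% and 155%. Without rs34173062_7 SHARPIN changed by −0.64 (adjusted p = 0.00953 by edgeR) and MAF1 no longer passed (−0.27, 0.393). Without rs34173062_2 they changed by −2.43 and −0.80. ZC3H3 missed the threshold in lanes 1 to 6 alone (0.34, adjusted p = 0.451 by edgeR). The placed rs11039225 sgRNAs, 2 of 3, lay on chromosome 11 (47409028 to 47409073), inside SLC39A13 and in an exon of the antisense gene AC090559.1, 1.92 kb from the TSS of SLC39A13.

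TMEM219, a membrane receptor of IGFBP3, was lower under rs4318227 by less than the other pairs, at 40.0 ± 3.77 against 49.8 ± 9.16 CPM (−0.37 ± 0.09, adjusted p = 0.00622 by edgeR). The single placed sgRNA of that region lay in the 5′ UTR of TAOK2 (chromosome 16, 29973674 to 29973693), 32.8 kb from the TSS of TMEM219. No sgRNA of that region lay below every non-targeting sgRNA, 1 of which left TMEM219 at 26.4%, and the exact permutation test gave p = 0.128 (n = 3 against 23). The call ended without rs4318227_1 (−0.36, adjusted p = 0.187) and without rs4318227_2 (−0.32, 0.375 by edgeR), by limma-trend, with all cells with a called sgRNA and in either set of lanes (adjusted p of 0.128 to 0.433). The exact test gave 0.000385 for the TSPAN14 and SLC39A13 pairs, 0.00154 for SHARPIN, 0.00231 for ZC3H3 and 0.00346 for MAF1 (exact permutation, n = 3 against 23).

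TSPAN14 was lower under 3 of the 76 regions. Under the rs7080009 region its 3 sgRNAs left 35.4%, 46.6% and 51.5% of the non-targeting mean, each below all 23 non-targeting sgRNAs. The fall (−1.14, 95% interval −1.41 to −0.88) overlapped that of the TSS sgRNAs (−1.03, −1.28 to −0.78), and the difference between them was not tested. The placed sgRNAs of the region lay at 80509604 to 80509819 on chromosome 10, inside TSPAN14 (80454166 to 80533123, plus strand), 55.5 kb from the TSS. That position is intronic in the protein-coding transcripts and exonic in 1 without coding sequence. Under rs9633740 TSPAN14 fell to 26.5 ± 8.53 CPM (−0.58 ± 0.10, adjusted p = 2.26e-07 over the 76 regions by edgeR; exact permutation p = 0.00192, n = 3 against 23). Its sgRNAs left 86.4%, 44.8% and 63.5%, and the change was −0.89 without rs9633740_1, −0.40 without rs9633740_2 and −0.55 without rs9633740_3, past the threshold each time. Under rs4318227 TSPAN14 stood at 32.1 ± 2.40 CPM (−0.37 ± 0.10, adjusted p = 0.00533 by edgeR; exact permutation p = 0.00308, n = 3 against 23), with 2 of 3 sgRNAs below all non-targeting sgRNAs. That region lies on chromosome 16, and without rs4318227_2 the call ended (−0.31, adjusted p = 0.226 by edgeR). It also ended with all cells with a called sgRNA (−0.10, adjusted p = 0.747) and in either set of lanes (0.0884 and 0.232 by edgeR). The next region, rs2452758, did not pass (−0.27 ± 0.12, adjusted p = 0.302 by edgeR).

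**Figure D2:**
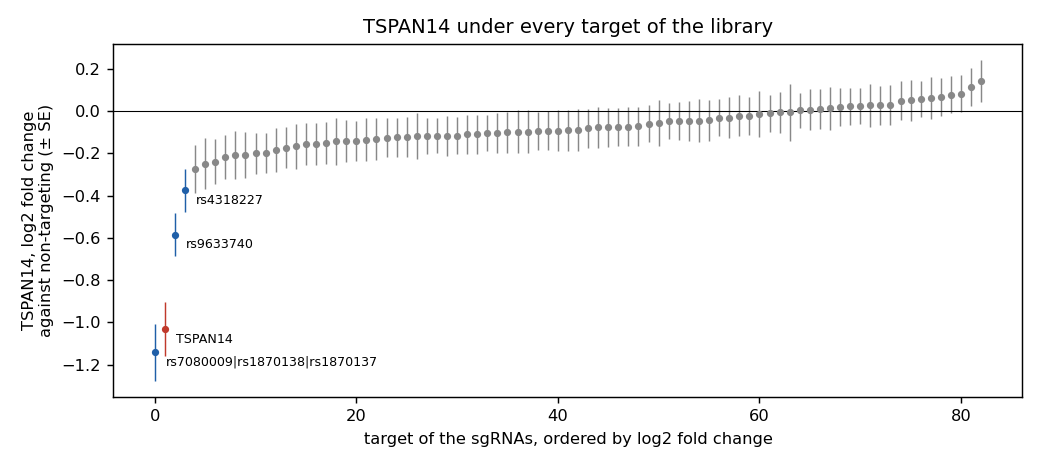
Log2 fold change of TSPAN14 with its SE under each of the 76 regions and 7 TSS targets, ordered by value. The TSPAN14 TSS sgRNAs (red) and the 3 regions past the threshold (blue) are named, with the rs7080009 region lowest at −1.14, and all other targets are grey.

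**Figure D3:**
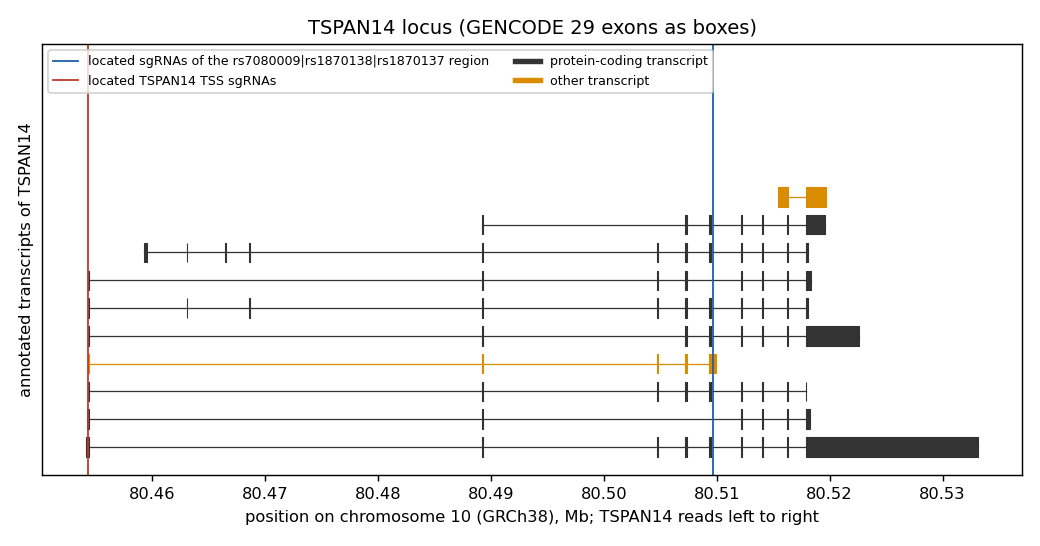
Annotated transcripts of TSPAN14 on chromosome 10 (GRCh38, position in Mb), with exons as boxes, protein-coding transcripts in black and others in orange. The red line marks the placed TSS sgRNA and the blue line the placed sgRNAs of the rs7080009 region, 55.5 kb downstream of the TSS.

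The SYVN1 sgRNA changed by far the most genes of the TSS targets: 46 were higher and 3 lower, against 12 changes over the other 6 targets together. By limma-trend, given in the closing section, the other targets together gave more changes than SYVN1. The 2 largest rises were those of ER chaperones. HSPA5 (ENSG00000044574), the main ER chaperone, rose from 223 ± 14.1 to 672 CPM (log2 1.59 ± 0.06, adjusted p = 2.02e-80 by edgeR) and HSP90B1, the ER form of HSP90, from 678 ± 25.7 to 1560 CPM (1.20 ± 0.05, 9e-73). Also higher by edgeR at adjusted p of 0.000223 or less were HERPUD1 (1.08 ± 0.10), a component of ER-associated degradation, the cochaperone SDF2L1 (1.05 ± 0.07), the secreted ER protein MANF (0.96 ± 0.07) and the disulfide isomerase PDIA4 (0.95 ± 0.08). The transcription factors DDIT3 (0.71 ± 0.13) and XBP1 (0.66 ± 0.10), the lectin chaperone CALR (0.65 ± 0.05) and the COPII coat subunit SEC24D (0.62 ± 0.12) followed.

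Fewer genes fell under the SYVN1 sgRNA. HCFC1R1 fell by 0.54 ± 0.14 on the log2 scale, PHF20, a chromatin reader, by 0.29 ± 0.07 and SELENOH, a nuclear selenoprotein, by 0.24 ± 0.06 (adjusted p = 0.0281, 0.0267 and 0.0321 by edgeR). Of the 18 measured genes of the unfolded protein response list, 11 were higher and none lower, both over all genes and adjusted over the list alone (camera adjusted p = 9.62e-106, and adjusted p = 5.89e-47 with an estimated correlation). ATF4, a transcription factor of the same response (log2 0.01 ± 0.09), its target ATF3 (−0.13 ± 0.34) and SEL1L, the partner of SYVN1 in the ligase complex (0.23 ± 0.14), did not pass; these members were chosen after their values were seen. All of this rests on 1 sgRNA in 335 cells.

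**Figure D4:**
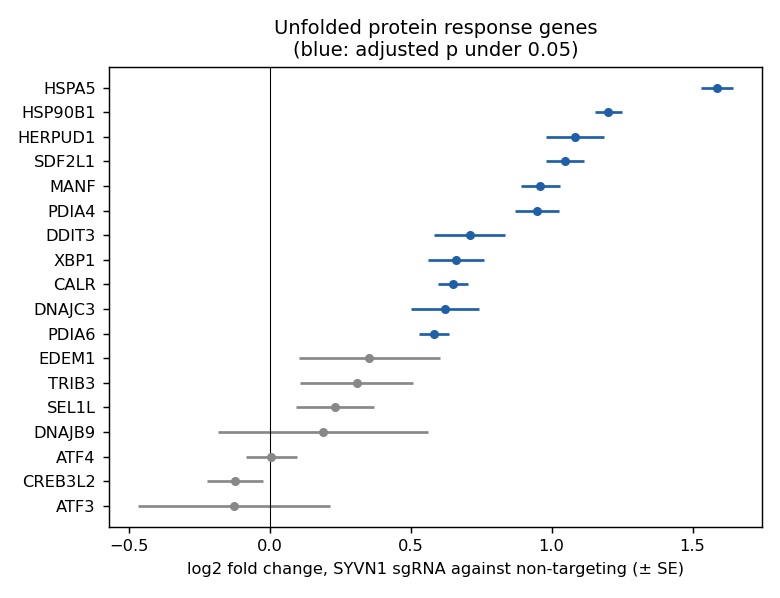
Log2 fold change with its SE of the 18 measured genes of the unfolded protein response list under the single SYVN1 sgRNA against 23 non-targeting sgRNAs. Blue points have an adjusted p under 0.05 over all genes and grey points do not. HSPA5 (1.59) and HSP90B1 (1.20) lead, and ATF4 lies at 0.01.

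The other TSS targets changed few genes, 12 in all, or 7 without their own genes. SNX1 sgRNAs raised TTF2, a transcription termination factor, to 56.2 ± 5.45 from 44.2 ± 3.62 CPM (0.37 ± 0.08, adjusted p = 0.0238 by edgeR), with 2 of 3 sgRNAs above every non-targeting sgRNA. This call ended without SNX1_2 (0.33, adjusted p = 0.899) and without SNX1_3 (0.36, 0.47 by edgeR), with changes of similar size. The RPA1-SMYD4 sgRNAs raised GAPDH, the glycolytic dehydrogenase, to 6085 ± 76.7 from 5397 ± 159 CPM (0.20 ± 0.04, 0.000665) and RPL8, a protein of the large ribosomal subunit, to 4581 ± 137 from 4237 ± 119 CPM (0.13 ± 0.03, 0.0119), in all 3 sgRNAs by edgeR. Without RPA1-SMYD4_3 GAPDH stood at 0.17 (adjusted p = 0.265) and RPL8 at 0.12 (0.597), similar rises that no longer passed. RPL8 also missed the threshold without RPA1-SMYD4_1 (0.15, 0.0533) and RPA1-SMYD4_2 (0.12, 0.194 by edgeR). Over all settings the call was lost in 9 of 19 for TTF2, 4 of 19 for GAPDH and 11 of 19 for RPL8. RAB1A, TSPAN14 and CLU sgRNAs changed their own gene alone.

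The remaining calls were chosen for naming after their values were seen. Under SNX1 sgRNAs FADS1, a fatty acid desaturase, was lower (−0.65 ± 0.11, adjusted p = 4.78e-05 by edgeR), but SNX1_2 alone left 9.87% and the others 95.4% and 105%. CSTB, a cathepsin inhibitor, was lower (−0.32 ± 0.06, 0.000751 by edgeR), but SNX1_3 alone left 38.7% and the others 95.9% and 105%. HERC5, an interferon-induced ligase, was higher under BIN1 (1.86 ± 0.29, 1.99e-05) and IFIT1, also interferon-induced, under RPA1-SMYD4 (2.19 ± 0.43, 0.0223 by edgeR), each in 2 of 3 sgRNAs and from 5.01 and 3.77 CPM. Each call ended without 1 sgRNA: FADS1 without SNX1_2 (0.02), CSTB without SNX1_3 (0.03), HERC5 without BIN1_3 (1.03) and IFIT1 without RPA1-SMYD4_3 (1.43).

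**Figure D5:**
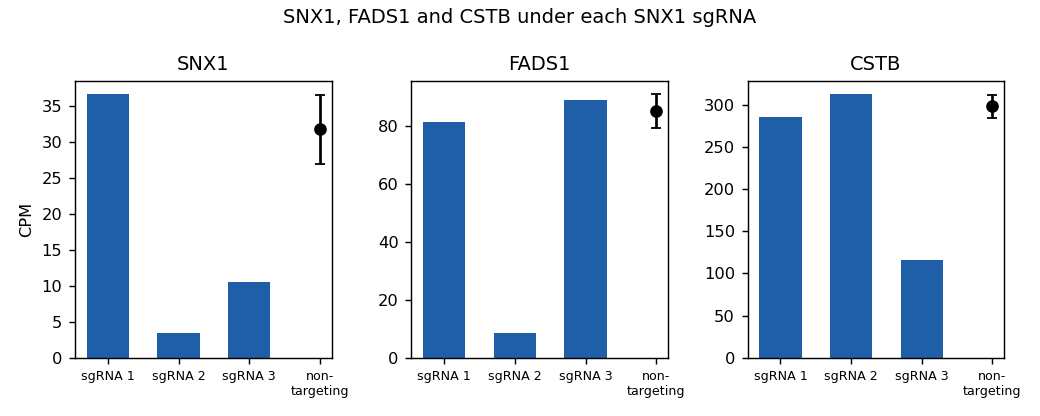
CPM of SNX1, FADS1 and CSTB under each of the 3 SNX1 sgRNAs (bars), with the mean and SD of the 23 non-targeting sgRNAs (black point and error bar). SNX1_2 left 10.8% of SNX1 and 9.87% of FADS1, and SNX1_3 left 33.0% of SNX1 and 38.7% of CSTB.

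Across all genes, 13 of the 76 regions gave at least 1 change, 17 in all, and 11 when p-values were adjusted over all regions together. The total of 17 did not exclude chance, since shuffled sgRNA labels reached up to 23. The largest by p was APP (ENSG00000142192), the amyloid precursor protein, under rs469420: it fell to 39.3 ± 13.9 from 101 ± 8.47 CPM (−1.26 ± 0.08, adjusted p = 1.75e-38 by edgeR), with 53%, 25.6% and 38.1% left by the 3 sgRNAs. This gene was chosen after its value was seen, and the coordinates of rs469420 are not given since its sgRNAs matched no transcript. Beyond the pairs above, rs34173062 raised OSBPL8, a lipid transfer protein of the ER (0.28 ± 0.06, 0.0163 by edgeR), which lies on chromosome 12. The rs3935067 sgRNAs raised MDM2, the ligase that degrades p53 (0.69 ± 0.14, 0.0345 by edgeR), to 82.6 ± 34.4 from 50.4 ± 17.0 CPM. Leaving out 1 sgRNA ended both calls: OSBPL8 stood at 0.23 without rs34173062_2 (adjusted p = 0.671 by edgeR), close to its full value, and MDM2 at 0.38 without rs3935067_2 (0.977).

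The other regional changes were named after their values were seen. FERMT2 was lower under the region named for rs8019279 (−0.31 ± 0.06, adjusted p = 0.0326 by edgeR) in 2 of 3 sgRNAs. CIAO2A, of cytosolic iron-sulfur assembly, was lower under the region named for rs332262 (−0.44 ± 0.08, 0.00145 by edgeR), and TTC37, of the RNA-degrading Ski complex, under the region named for rs9271579 (−0.40 ± 0.08, 0.00237). B4GAT1, a glycosyltransferase, was higher under rs3935067 (0.56 ± 0.12, 0.0345), MDM2 under rs916888 (0.70 ± 0.14, 0.016), IFIT1 under rs76842328 (2.40 ± 0.38, 8.31e-05) and HERC5 under rs1377416 (1.53 ± 0.29, 0.0137 by edgeR). KRT17, a keratin, was higher under rs74685827 (2.68 ± 0.28, adjusted p = 4.12e-14 by edgeR) through rs74685827_1 alone, at 69.4 CPM, with 4.02 and 1.60 CPM under the others and 3.93 ± 2.87 CPM under non-targeting sgRNAs. Without that sgRNA KRT17 stood at −0.48. With rs74685827_1, 2.79% of cells held a KRT17 UMI, against 2.68% of non-targeting cells, so the rise lay in few cells. HERC5 under rs1377416 likewise came from 1 sgRNA, rs1377416_3, at 31.5 CPM against 6.40 and 4.52 CPM, and stood at 0.24 without it. Each of the others lost its call without 1 sgRNA, and MDM2 under rs916888 turned to −0.21 in lanes 7 to 12 alone. By edgeR these stood at −0.24 for FERMT2 (without sgRNA 1 of the region, adjusted p = 0.993), −0.40 for CIAO2A (sgRNA 2, 0.566) and −0.31 for TTC37 (sgRNA 3, 0.858). B4GAT1 stood at 0.46 (without rs3935067_2, adjusted p = 0.957), MDM2 at 0.62 (rs916888_1, 0.95) and IFIT1 at 1.75 (rs76842328_2, 0.822 by edgeR). Over all settings B4GAT1 lost its call in 11 of 18, FERMT2 in 9 of 19, OSBPL8 in 7 of 19 and MDM2 under rs3935067 in 11 of 19. In 4 of the 17 changes every sgRNA of the region lay beyond every non-targeting sgRNA.

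Gene lists other than the unfolded protein response moved little. With the preset correlation, 29 of 176 list tests passed and with an estimated correlation 3. The second was the glycolysis and hypoxia list under BIN1 sgRNAs, higher by a median log2 of 0.08 (adjusted p = 2.26e-05, and adjusted p = 0.0488 with an estimated correlation). Adjusted over the list alone 2 of its 16 members rose: BNIP3, a mitophagy receptor (0.15 ± 0.04, adjusted p = 0.00482 by edgeR), and LDHA, lactate dehydrogenase (0.09 ± 0.03, 0.0141 by edgeR), and none did over all genes. The third was the list of TSPAN14-type tetraspanins, ADAM10 and Notch genes under TSPAN14 sgRNAs, which holds TSPAN14 itself (adjusted p = 0.00301, and 0.0488 with an estimated correlation). TSPAN14 was its only member past the test, with JAG1, a Notch ligand (−0.58 ± 0.27), TSPAN10 (−0.49 ± 0.26) and the protease ADAM17 (−0.24 ± 0.16) not passing. The same list under the rs7080009 region passed with the preset correlation (adjusted p = 0.00564) and not with an estimated one (adjusted p = 0.068).

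Among the lists lost with an estimated correlation was that of cytosolic ribosomal proteins, higher under RAB1A sgRNAs by a median log2 of 0.06 (adjusted p = 4.35e-19, and adjusted p = 0.114 with an estimated correlation of 0.50 between its genes). Adjusted over the list alone 16 of its 26 members rose and over all genes none. It also passed under SNX1, RPA1-SMYD4, TSPAN14, BIN1 and rs11039225, with adjusted p of 0.452, 0.593, 0.703, 0.843 and 0.684 when the correlation was estimated. The G2/M list was lower under rs4318227 (median −0.07, adjusted p = 9.22e-10, and adjusted p = 0.407 with an estimated correlation), with none of its 52 members past the test. The p53 target list was lower under SYVN1 (median −0.23, adjusted p = 0.000832, and adjusted p = 0.154 with an estimated correlation), with none of 15 members past the test. It was also lower under RAB1A (median −0.14, adjusted p = 0.0142, and adjusted p = 0.361 with an estimated correlation) and under the rs7080009 region (median −0.09, adjusted p = 0.0048, and adjusted p = 0.28 with an estimated correlation). The RAB1A list call ended without RAB1A_1 (adjusted p = 0.165). Adjusted over the list alone, MDM2 (−0.92 ± 0.25 and −0.61 ± 0.22) and CDKN1A, an inhibitor of cell cycle kinases (−1.18 ± 0.45 and −1.06 ± 0.40), fell under both by edgeR, and BAX, a promoter of apoptosis, under the region (−0.15 ± 0.06). None of the members passed over all genes.

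The number of cells per sgRNA was compared between classes. Region sgRNAs were in 1.26 times as many cells as non-targeting sgRNAs (median 248 against 200 cells, permutation p = 0.00136, n = 227 and 23), and TSS sgRNAs in 0.963 times as many (median 181, permutation p = 0.805, n = 19 and 23). The RPA1-SMYD4 sgRNAs were in 0.568 times as many cells, within the spread (exact permutation p = 0.168, adjusted p = 0.875, n = 3 against 23), and the SYVN1 sgRNA in 1.79 times as many (exact permutation p = 0.25, n = 1 against 23). The share of each sgRNA in the starting pool was not used here, so these ratios do not measure growth.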

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

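The test of 2 vectors in 1 cell, given below, was chosen after its result had been seen. Of 16 effects tested, 14 moved the same way, with a range that leaves out 100%, in data outside the report's comparisons: 12694 barcodes in which 2 sgRNAs were called, which otherwise entered 1 alternative setting. The effects were picked from the calls for a large change with every sgRNA on 1 side. Those under SYVN1 share 1 sgRNA and the same 104 barcodes, so they are not separate checks. Each value here is the level of a gene in barcodes where 1 of the 2 sgRNAs had the named target, as a percentage of its level in the other barcodes with 2 sgRNAs. The range in brackets covers counting error only. The chaperone genes raised by the SYVN1 sgRNA were higher in such barcodes too: HSPA5 at 256% (240 to 274), HSP90B1 at 189% (180 to 197), MANF at 178% (161 to 197), SDF2L1 at 174% (160 to 190), PDIA4 at 172% (150 to 195) and HERPUD1 at 171% (140 to 206).

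The lowered genes tested in these barcodes were lower there as well, while others, SNX1, RPA1, SMYD4, MAF1 and TMEM219 among them, were not tested in them. Among TSS targets RAB1A stood at 56.7% (48.6 to 65.7), CLU at 61.1% (37.2 to 94.6), BIN1 at 76.1% (63.0 to 91.2) and TSPAN14 at 80.5% (68.0 to 94.6). Among regions SLC39A13 stood at 64.6% (52.4 to 78.8) under rs11039225, SHARPIN at 64.8% (51.2 to 81.0) under rs34173062, TSPAN14 at 65.9% (54.9 to 78.5) under the rs7080009 region and APP at 66.2% (59.3 to 73.7) under rs469420. IFIT1 under rs76842328 moved the other way, to 47.9% (21.8 to 91.3, from 9 UMIs) against 441% in cells with 1 sgRNA. In all, 15 of 16 such ranges left out 100%, the exception being CBLB under SYVN1 at 113% (61.5 to 190).

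The effects were smaller in barcodes with 2 sgRNAs than in cells with 1, which droplets with 2 cells would bring about. The choice of large effects may add to this. Over 10 targets the median share of the effect kept was 0.617 (97.9% interval 0.369 to 0.719), and a droplet with 1 cell of each kind would keep near 0.5. Such barcodes also held 1.57 times the UMIs of those with 1 sgRNA (1.47 to 1.67 over the lanes), which argues against 2 vectors in 1 cell as the whole account. Free sgRNA transcripts counted as a second sgRNA stay open for part of the barcodes, since the sgRNA with fewer UMIs kept 0.474 of the effect with a wide interval (0.0891 to 0.744). No biological explanation was tested.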

How the results depend on the processing

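Leaving out non-targeting sgRNAs with 2 or more changes of their own, leaving out sgRNAs in under 100 cells, and limma-trend without such sgRNAs were chosen after the data were seen; the other settings were planned. No paired analysis was possible because the numbers in sgRNA names mark separate vectors and join none of them to a non-targeting sgRNA. TSPAN14 under the rs7080009 region kept its fall past the threshold in all 20 settings tried (−0.65 to −1.29), as did APP under rs469420 in all 19. The own genes lowered numbered 5 to 7, the region-gene pairs 5 to 8, the regions that changed TSPAN14 2 or 3, and cells per region sgRNA stood at 1.26 to 1.28 times the non-targeting number.

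Counts of changes moved more, and the cause was not tested except where given. By limma-trend SYVN1 gave 22 changes, the other TSS targets 1715, all TSS targets 1737 and the regions 314. Without sgRNAs in under 100 cells limma-trend gave 23 for SYVN1, 45 for the other TSS targets and 64 for regions, and its count under RPA1-SMYD4 fell from 1686 to 5, so these sgRNAs carried most of that rise. Lanes 7 to 12 alone, with fewer cells, gave 19 changes for SYVN1, 6 for the other TSS targets and 25 for all, and lanes 1 to 6 alone 6 for the others. The region changes numbered 11 by DESeq2, 34 with genes of a mean count of 1 or more, 26 against odd non-targeting sgRNAs and 11 with p-values adjusted over all regions together. Lanes 1 to 6 alone kept 6 of the 17 region changes and lanes 7 to 12 alone 5. Of the list tests 3 passed with an estimated correlation and 7 by fry.

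With 1 sgRNA of each target left out, the other TSS targets gave 5 to 12 changes, all TSS targets 12 to 63 (12 where the only SYVN1 sgRNA is left out) and lists 19 to 33. Some single genes turned over in this way: CSTB under SNX1 ranged from −0.63 to 0.026, FADS1 under SNX1 from −1.24 to 0.025, and KRT17 under rs74685827 from −0.48 to 3.29 and TAOK2 under rs4318227 from −0.34 to 0.14, while the G2/M list under CLU had adjusted p from 9.67e-14 to 0.609. MDM2 under rs916888 stood at −0.21 in lanes 7 to 12 alone, TAOK2 under rs4318227 at 0.28 there, and SMYD4 at 0.019 with all cells with at least 1 called sgRNA. RPA1 missed the threshold in lanes 7 to 12 (−0.18, adjusted p = 0.123), ZC3H3 in lanes 1 to 6 (0.34, 0.451) and TMEM219 by limma-trend (adjusted p = 0.377), while without non-targeting sgRNAs with 2 or more changes TMEM219 stood at −0.41 (0.00026 by edgeR). TSPAN14 under rs4318227 was lost with all cells with a called sgRNA (adjusted p = 0.747) and in either set of lanes (0.0884 and 0.232 by edgeR). The comparison with sgRNAs of other chromosomes was not run for regions without a position.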

Other observations

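Tests chosen after their results had been seen were those of a response to lower SNX1, of sgRNA binding at FADS1 and CSTB, of the overlap of SYVN1 with FAU, and all shuffles of sgRNA labels. The genes of the first 2 paragraphs were also chosen after their values were seen. Beyond the chaperones named in the report, the SYVN1 sgRNA raised the disulfide isomerases PDIA6 (log2 0.58 ± 0.05), PDIA3 (0.54 ± 0.06) and P4HB (0.36 ± 0.05) and the oxidoreductase TXNDC5 (0.33 ± 0.09). It raised the HSP40 cochaperone DNAJB11 (0.53 ± 0.08) and DNAJC3 (0.62 ± 0.12), an inhibitor of the kinase PERK, as well as HYOU1 (0.59 ± 0.12), an ER member of the HSP70 family. CANX (0.44 ± 0.06), a lectin chaperone like CALR, and the prolyl isomerase PPIB (0.40 ± 0.05) rose too. The COPII coat subunit SEC31A (0.46 ± 0.08), the coatomer subunits COPB1 (0.35 ± 0.07) and COPA (0.33 ± 0.08) and the KDEL receptor KDELR3 (0.46 ± 0.10) were higher, with adjusted p of 0.0374 or less for every gene of this paragraph by edgeR. These genes were picked from the 49 changes and no group of them was tested beyond the fixed lists.

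Region sgRNAs placed inside CLU and TAOK2 did not change these genes past the threshold, and other genes that hold a placed region are not described here. The region named for rs1532276, rs1532277 and rs1532278 lies inside CLU on chromosome 8 (27608554 to 27608847), 6.33 kb from its TSS, and CLU stood at 10.6 ± 1.63 against 8.79 ± 2.24 CPM (log2 0.26 ± 0.18, 95% interval −0.08 to 0.61, adjusted p = 0.875 by edgeR). The rs2279590 sgRNAs lie 16.3 kb from the TSS of CLU, inside the gene (27598606 to 27598800), with CLU at −0.20 ± 0.19 (interval −0.57 to 0.17, adjusted p = 0.917 by edgeR) and 1 of 3 sgRNAs below every non-targeting sgRNA. The placed rs4318227 sgRNA lies in the 5′ UTR of TAOK2, a kinase, 0.042 kb from its TSS, with TAOK2 at 9.89 ± 2.66 against 10.1 ± 2.34 CPM (−0.08 ± 0.18, interval −0.44 to 0.29 by edgeR; exact permutation p = 0.93, n = 3 against 23). Its sign turned without rs4318227_2 (0.14) and in lanes 7 to 12 alone (0.28). The intervals of TAOK2 and of CLU under rs2279590 do not exclude falls of up to 0.44 and 0.57 on the log2 scale.

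Single SNX1 sgRNAs lowered genes that the other SNX1 sgRNAs left in place, and binding of the sgRNA at those genes is the explanation that its test favoured. SNX1_2 left FADS1 at 9.87% of the non-targeting level, with a UMI in 7.11% of its 225 cells against 58.4% of non-targeting cells, and lowered it in all 12 lanes. SNX1_3, which left 33.0% of SNX1, left FADS1 at 89.2 CPM, within the non-targeting range, which argues against a response to lower SNX1. The PAM side of SNX1_2 matched 11 bases beside an NGG in FADS1 (chromosome 11, 61816660 to 61816679), and that of SNX1_3 10 bases in CSTB (chromosome 21, 43776099 to 43776118), matches as long as in at most 0.7% of 1000 other genes. By the rule set beforehand, 5 changed genes or fewer under such an sgRNA alone count against a single clone. SNX1_2 alone changed 5, on the bound itself, and SNX1_3 alone 3, with SNX1 among them in both. Both counts meet the rule, but with 1 of them on its bound a clone was left open. A clone that changes few genes would escape this count.

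The same search over other genes that single TSS or non-targeting sgRNAs lowered to 50% or less left binding open. DYNLT3 under SNX1_2 (41.6%) and RCN3 under non-targeting_00022 (26.7%) had matches of 11 bases, 2 of 10 genes (one-sided exact binomial p = 0.0861). FADS2 under SNX1_2 (33.7%) shares the FADS1 site and was left out after the result was seen; kept in, 3 of 11 gave an exact binomial p of 0.0152. GLIPR1 under non-targeting_00004 (19.1%), ARL6IP1 (36.0%) and TMEM219 (26.4%) under non-targeting_00022, and CPA4 (38.2%) and PSG4 (22.2%) under BIN1_1 had no such match in their transcripts. N6AMT1 under SNX1_2 (34.8%), MT1X under SNX1_3 (45.0%) and NHEJ1 under non-targeting_00011 (0%) had none either. Matches in transcripts thus did not cover every gene that SNX1_2 or SNX1_3 lowered. Promoters and introns were not searched.

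The rise of ER stress genes without a fall of SYVN1 itself was a property of most cells with that sgRNA. HSPA5 lay above the non-targeting median in 79.1% of 335 cells (95% interval 74.4 to 83.3, counting error of cells only) against 44.7% of non-targeting cells, while stress in 50% of the cells allows at most 72.4%, which argues against a stressed minority. Of the 23 non-targeting sgRNAs 0 gave as many as the 49 changes when each was tested alone by edgeR, the most being 4, which argues against the spread of a single sgRNA. SYVN1 shares 694 bases of its 3′ end with FAU on the same strand, and FAU stood at 102%, so a fall of SYVN1 hidden by UMIs of FAU cannot be told apart from no fall. A direct effect of this sgRNA on another gene was not tested.

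Shuffled sgRNA labels, 100 splits each with the real 1 included, tell whether chance alone gives as many calls. Chance is excluded for the count of 7 lowered own genes of TSS targets (highest other split 1, as many in 1 split). The same holds for the count of 6 region-gene pairs (highest other 3, as many in 1). That count does not bear on single pairs, such as TMEM219 under rs4318227 (exact permutation p = 0.128, n = 3 against 23). Chance is not excluded for the 17 changes under regions (highest other 23, as many in 9). For the 3 regions that changed TSPAN14 as many came in 2 splits (highest other 3). A shuffled split thus also reached 3, so chance can give that count, and the count does not bear on rs4318227 alone. The 12 changes under TSS targets without SYVN1 gave a highest other of 5, with as many in 1. So did the 7 of them that are not own genes. The SYVN1 sgRNA kept its label in both of these shuffles, a choice made after a first shuffle that moved it too. That first shuffle reached 26 for both, with as many in 8 and 9 of 100 splits, and did not exclude chance. It also moved the SYVN1 sgRNA, which alone changed 49 genes, into other targets, so it cannot decide. Chance therefore stays open for the 12 and the 7 as totals. The own genes among the 12 belong to the lowered own genes, for whose count chance is excluded above. Each of the 7 calls that are not own genes ended without 1 sgRNA of its target. Other values stand without explanation. KRT17 had a UMI in 2.79% of the 323 cells with rs74685827_1 and in 2.68% of non-targeting cells, with means of 0.796 and 0.0462 UMIs. The rise thus lay in a small share of the cells and was seen in 4 of the 12 lanes. ISG15, an interferon-induced protein, stood at 492% under non-targeting_00022, and FBXO32, a ubiquitin ligase of muscle wasting, at 578% under rs2075659_1. CCDC90B stood at 17.0% under 1 sgRNA of the region named for rs34779859 and rs6733839. Tested alone by edgeR, 184 of 227 region sgRNAs and 16 of 23 non-targeting sgRNAs changed no gene.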
